A study of Equus caballus with 33 samples.

How the data were processed

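Gene expression was measured in equine articular cartilage explants with an Affymetrix microarray. Per the labels' protocols, explants were kept in medium for 48 h, then cultured with recombinant equine IL-1β at 10 ng/mL or in medium without it. A pair of explants from each treatment and time was minced and digested with trypsin and then collagenase before the cells were lysed in TRIzol, so that transcripts that respond to tissue digestion could differ from those in intact cartilage. Per the labels, amplified and biotinylated sense-strand cDNA was made from 2 ng of total RNA per sample, a low input.

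The authors deposited a table of log2 expression values, 1 column per array, with 25923 probe sets and 33 arrays. Per the submitters' processing notes, Affymetrix Expression Console, RMA and limma were used, with no version or role given. RMA corrects background, normalises arrays between each other by quantiles and summarises probes into probe sets. The log base is not given in the sources used here, and log2 was inferred from the range of the values, 1.50 to 13.9. RMA compresses changes near the lowest and highest signals, and quantile normalisation removes a change shared by most genes. The deposited values were not normalised again, with array medians of 5.16 to 5.38 and interquartile ranges of 3.23 to 3.81. No measure of signal over background was used here, so that folds of genes near the lowest signals can be understated. Scanner files and scan batches were not analysed here.

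Probe sets were named from the platform annotation, which can be old. Of the probe sets, 16789 had 1 gene symbol, 343 had several and were not named, and 8791 had none listed. All were kept in the tests, which can include control probe sets. A gene symbol was represented by the probe set with the highest mean over all arrays, which gave 16661 symbols. No genome was used here, and no coordinates are given.

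Groups and times came from the sample titles. The labels give 3 horses, and each replicate number goes with 1 prefix, read as an experiment number, in the sample descriptions. Samples of 1 number were therefore taken to come from 1 horse, an inference that no label states in words. Whether arrays of 1 number vary together was checked on the deviations from the group means. A batch that goes with the experiment number would give the same, so that this check cannot tell a horse from a batch. The median correlation between arrays of the same number in different groups was 0.164 over 165 pairs, and -0.0841 over 330 pairs of different numbers. The lowest correlation between stimulated and unstimulated explants of the same day and number was 0.0781 over 15 pairs, and 33 of 33 arrays correlated best with their own number. The correlation estimated by duplicateCorrelation was 0.0727.

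Comparisons were made in limma 3.58.1 under R 4.3.3, with lmFit and eBayes and 1 mean per group over all 33 arrays, which leaves 22 residual degrees of freedom. This fit held no term for the replicate number, so that arrays of 1 number at different days counted as independent. For the average over days, its standard errors and p-values therefore do not measure the spread of the effect between replicate numbers. Pooling the spread over 11 groups was chosen because each group holds 3 arrays, where an exact permutation test of 3 against 3 cannot give a p below 0.1. The contrasts were stimulated minus unstimulated at each day, their average over the 5 days, day 27 minus day 3 of that difference, and changes in unstimulated explants between days 0 and 3 and days 3 and 27. Moderated F-tests asked whether the difference varied between days and whether unstimulated explants varied over the 6 times. All p-values were two-sided and adjusted by Benjamini-Hochberg over all probe sets, with 0.05 as the threshold.

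Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over 23 lists of pathways, functions and tissue digestion and separately over 9 lists of cell type markers, and again with the correlation estimated per list. Where the counts adjusted over the list alone are not given for a list in the average over days, they were equal to those over all probe sets. Genes of the lists that no single-symbol probe set represents, 70 in all and CCL2 and NFKBIA among them, were not analysed here. The genes named in the text were chosen by a rule. It takes 24 fixed genes (22 with a probe set), the 8 highest and 8 lowest differences among genes that passed with the same sign in all 3 numbers for each contrast, the 10 smallest p of each F-test and up to 4 members with the smallest p per list. The groups, contrasts, gene lists, naming rule and alternatives other than the one without the day 27 array were chosen before the data were examined.

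The alternatives were the replicate number as a fixed block (20 residual degrees of freedom) or a random block, only probe sets above the median signal, quantile normalisation once more, eBayes with trend and robust fitting, array weights, only the arrays compared, an added 2-fold threshold, each replicate left out in turn, an estimated correlation and averaged probe sets for the lists. With a random block or a trend, lists were tested by the preranked form of camera. Apart from the fixed block and the estimated correlation, the alternatives tested lists for the average over days only. An alternative without the unstimulated array of day 27, replicate 3, which had an array weight of 0.305, was added after the data were seen. The procedure was tested on simulated data with 50 probe sets changed at each size. For the average over days it recovered 78% of changes of 0.5 and 98% of changes of 1, with 9 false calls. At day 3 it recovered 12%, 68% and 96% of changes of 0.5, 1 and 2, with 8 false calls. At day 27 it recovered 8%, 52% and 96%, with 6 false calls. The simulated noise was independent between probe sets and between arrays, with no shift shared by arrays of a replicate. These rates therefore need not hold for the deposited data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.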

Results

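The data were microarray measurements of gene expression in articular cartilage explants of the horse. Cartilage is the load-bearing tissue of the joint, and its only resident cell is the chondrocyte. Interleukin-1β (IL-1β) is an inflammatory cytokine used to model joint disease in culture. Explants from the distal metacarpal bone of 3 horses without evidence of joint disease were cultured with recombinant equine IL-1β at 10 ng/mL or without it. Both kinds were harvested at 5 times, from day 3 through days 9, 15 and 21 to day 27, and unstimulated explants were also taken at day 0. The 33 arrays fell into 11 groups of 3, of which 15 arrays came from stimulated and 18 from unstimulated explants. Array medians lay between 5.16 and 5.38 on the log2 scale. Correlations between arrays of a group ranged from 0.960 to 0.989, and 0 pairs of arrays held identical values. The number of arrays limits the precision of each value.

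Stimulated and unstimulated explants were separated along the first principal component, which held 32.7% of the variance. Unstimulated explants at day 0 had a mean score of -13.7 ± 2.73 (SD, n = 3). The mean score of unstimulated explants was -24.8 ± 4.39 at day 3, -42.8 ± 5.43 at day 15, -41.87 ± 5.83 at day 21 and -39.05 ± 10.24 at day 27. That of stimulated explants was 24.9 ± 2.24 at day 3 and 50.1 ± 5.71 at day 27 (SD, n = 3 each). The second component held 8.42% of the variance, and the array of unstimulated explants at day 27, replicate 3, stood apart on it.

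**Figure D1:**
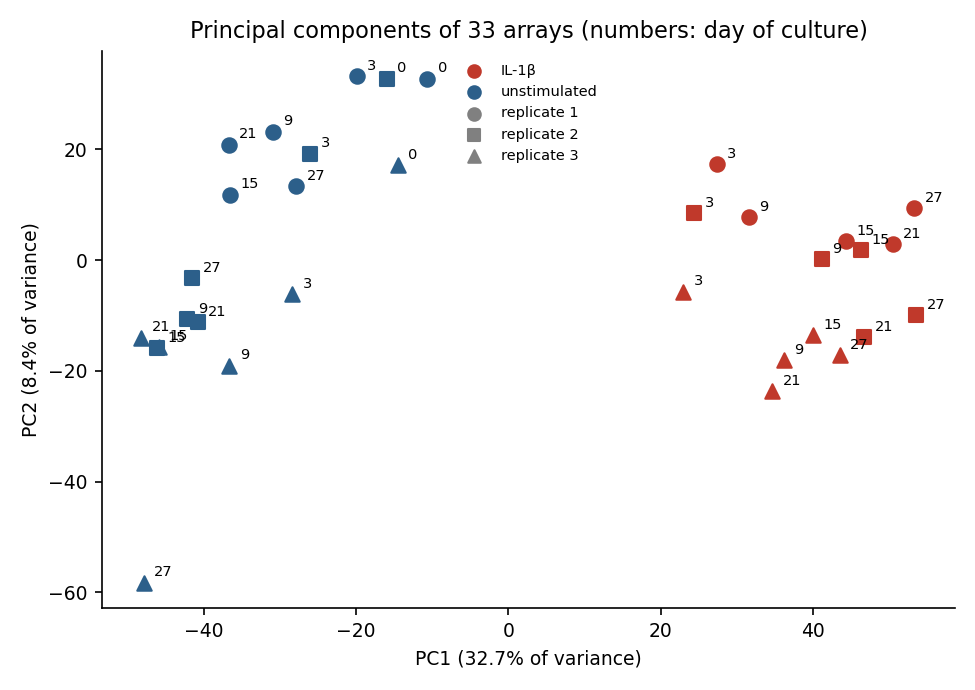
Scores of the 33 arrays on the first and second principal components, with each point an array, colour giving the stimulation, shape the replicate and the printed number the day of culture. The 15 stimulated arrays lie on the positive side of the first component and the 18 unstimulated arrays on the negative side.

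The design asks which genes differ between stimulated and unstimulated explants. Averaged over the 5 days, the lists of matrix-degrading proteases, chemokines and NF-kB genes shifted upwards with IL-1β and those of cartilage matrix and ribosomal protein genes downwards. Differences are given on the log2 scale as stimulated minus unstimulated, with the standard error of the limma fit after the ± sign and n = 3 arrays per group. For the average, arrays of the same replicate number at the 5 days counted as independent. This error therefore does not measure the spread of the effect between replicate numbers. MMP1, an interstitial collagenase, had the largest rise among the named genes, at 7.88 ± 0.17 (adjusted p = 3.9e-22). Its signal at day 3 was 13.09 ± 0.16 with IL-1β against 6.25 ± 1.01 without it (SD, n = 3), close to the highest value of any probe set, 13.9. S100A12, a neutrophil-associated calcium-binding alarmin, rose by 7.26 ± 0.19, and CCL20, a chemokine for dendritic cells and lymphocytes, rose by 6.22 ± 0.22. C1H15orf48 rose by 6.38, LOC100061699 by 6.15, the neutrophil chemokine CXCL6 by 6.10, LOC100061631 by 5.92 and the myeloid receptor gene TREM1 by 5.77. These 8 genes were higher in the stimulated explant in 15 of 15 pairs of the same day and replicate. Their choice by size and by the same sign in all 3 replicate numbers largely fixes that count.

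The largest falls were in SLC14A1, a urea transporter, at -5.49 ± 0.19 (adjusted p = 4.82e-18), and CILP, the cartilage intermediate layer protein, at -5.49 ± 0.26 (adjusted p = 3.03e-15). CHRDL2, a secreted BMP antagonist, fell by 5.25 ± 0.31, NELL2 by 4.84 ± 0.37 and the small proteoglycan gene OMD by 4.66 ± 0.44. APOA1, the main protein of high-density lipoprotein, fell by 4.57 ± 0.20, ITGBL1 by 4.40 ± 0.16 and PEBP4 by 4.36 ± 0.21. Each of these 8 was lower in the stimulated explant in all 15 pairs, which their choice by size and sign largely fixes as well.

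Among the 26 measured matrix-degrading proteases, 15 rose, 2 fell and 9 did not pass the test (15 and 3 adjusted over the list alone). MMP8, the neutrophil collagenase, rose by 4.67 ± 0.14, and MMP13, the main collagenase of cartilage, by 5.14 ± 0.53. ADAMTS4, an aggrecanase, rose by 3.56 ± 0.19 and the stromelysin MMP3 by 2.86 ± 0.24, whereas the membrane-bound MMP16 fell by 2.09 ± 0.11. ADAMTS5, the other main aggrecanase, was near the threshold at 0.72 ± 0.27 (adjusted p = 0.0451), with a higher value in 9 of 15 pairs. Its call was lost without any of the 3 replicates, with adjusted p of 0.0673, 0.276 and 0.076 without replicates 1, 2 and 3. The list as a whole was shifted upwards (limma camera adjusted p = 3.03e-05), and the shift held with an estimated correlation (adjusted p = 0.0186). Of the 10 protease inhibitors measured, 3 rose, 4 fell and 3 did not pass the test. TFPI2 rose by 3.43, TIMP1 by 0.73 and TIMP3 by 0.60, and the protease nexin SERPINE2 fell by 1.07. No shift of the inhibitor list was called (adjusted p = 0.986).

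Of 33 cartilage matrix genes, 22 fell, 2 rose and 9 did not pass the test (24 and 2 adjusted over the list alone), with a median difference of -0.866 (camera adjusted p = 1.01e-11, and 0.00496 with an estimated correlation). CHAD, which encodes the cell-binding matrix protein chondroadherin, fell by 3.88 ± 0.23, and CNMD, which encodes the anti-angiogenic chondromodulin, by 3.77 ± 0.11. The cartilage oligomeric matrix protein gene COMP fell by 2.17 ± 0.26, the minor fibrillar collagen gene COL11A1 by 1.91 ± 0.09 and COL2A1, the main collagen of cartilage, by 1.35 ± 0.22. ACAN, the gene of the proteoglycan aggrecan, fell by 1.11 ± 0.11. COL9A1 differed by -0.30 ± 0.12 and did not pass (adjusted p = 0.0671), but was called with the replicate block (adjusted p = 0.029). COL1A1, the main collagen of bone and fibrous tissue, differed by 0.04 ± 0.07 (adjusted p = 0.666).

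Hypertrophy and mineralisation genes, 17 of which were measured, fell in 9 cases and rose in 3, with 5 not passing the test. ALPL, the tissue-nonspecific alkaline phosphatase, fell by 3.40, COL10A1, the collagen of hypertrophic cartilage, by 2.33 and the parathyroid hormone receptor gene PTH1R by 2.22. The pyrophosphate regulators ENPP1 and ANKH fell by 2.05 and 1.20. The list's shift (camera adjusted p = 0.00126) was lost with an estimated correlation (adjusted p = 0.0799 with an estimated correlation). Among the 17 chondrocyte regulators, 8 fell, 3 rose and 6 did not pass the test (8 and 4 adjusted over the list alone). The Wnt antagonist gene FRZB fell by 2.61, NFATC2 by 2.07 and SOX6 by 1.14, while FOXO3 rose by 0.72. SOX9, the master regulator of chondrocyte fate, differed by 0.18 ± 0.10 (adjusted p = 0.207). The shift of the regulator list did not pass the test (adjusted p = 0.0501).

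Chemokines and NF-kB genes moved upwards without any member falling. Of 16 chemokines, 10 rose and 6 did not pass the test (11 adjusted over the list alone), CXCL1 by 5.08 ± 0.25, CXCL16 by 1.80 and CXCL8, which encodes interleukin-8, by 1.69 (camera adjusted p = 3.03e-05, and 0.0186 with an estimated correlation). Of 23 NF-kB target and feedback genes, 18 rose and 5 did not pass the test (19 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 6.15e-13, and 0.00317 with an estimated correlation). ZC3H12A, an RNase that limits cytokine transcripts, rose by 1.96, the transcription factor gene IRF1 by 1.84, and the NF-kB subunit genes NFKB1 and NFKB2 by 1.54 and 1.45. Cytokines and their receptors rose in 12 of 25 cases and fell in 3, with 10 not passing the test (13 and 4 adjusted over the list alone). IL6 rose by 4.37 ± 0.29, LIF by 2.04, IL1A by 1.55 and the receptor gene IL4R by 1.26 (camera adjusted p = 0.00383, and 0.0186 with an estimated correlation).

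Enzymes of prostaglandin and nitric oxide synthesis rose in 11 of 20 cases and fell in 3, with 6 not passing the test (12 and 3 adjusted over the list alone). NOS2, the inducible nitric oxide synthase, rose by 5.57 ± 0.18, PTGS2, which encodes cyclooxygenase-2, by 3.09 ± 0.20, PTGES by 2.80 and the phospholipase gene PLA2G4A by 2.75. That list was called with the preset correlation (adjusted p = 0.00146) and with an estimated correlation (adjusted p = 0.0445). Innate defence and complement genes split, with 6 of 20 higher, 8 lower and 6 not passing the test. PTX3, a soluble pattern recognition protein, rose by 5.63 ± 0.15, STEAP4 by 3.58 and S100A9 by 3.13. The median of this list was -0.128 whereas the direction of its test was upwards, and the test was not passed (adjusted p = 0.278). TNFAIP6, a hyaluronan-binding protein induced in inflammation, rose by 2.56 ± 0.29.

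Among metabolic and stress lists and the interferon response, the upward shift of glycolysis and hypoxia genes held with an estimated correlation and those of the other 4 lists called with the preset correlation did not. Of 27 glycolysis and hypoxia genes, 22 rose, 2 fell and 3 did not pass the test (22 and 3 adjusted over the list alone), with a median of 0.926 (camera adjusted p = 1.01e-11, and 0.0192 with an estimated correlation). The glucose transporter gene SLC2A1 rose by 1.98, GAPDH by 0.97, PGK1 by 0.94 and ALDOA by 0.91. Oxidative stress and metal handling genes rose in 9 of 14 cases and fell in 3, with 2 not passing the test. HMOX1, the inducible heme oxygenase, rose by 2.43, TXNRD1 by 1.73, GCLM by 1.68 and the ferritin gene FTL by 1.23 (camera adjusted p = 0.00236, but adjusted p = 0.105 with an estimated correlation). The unfolded protein response list had 12 of 19 genes higher, 3 lower and 4 not passing the test (13 and 3 adjusted over the list alone), among them ATF4 at 1.12 and EDEM1 at 0.98 (camera adjusted p = 0.00337, but adjusted p = 0.259 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 14 cases, with 5 not passing the test, among them SREBF2 at 1.11 and MSMO1 at 1.05 (camera adjusted p = 0.00383, but adjusted p = 0.305 with an estimated correlation). Interferon response genes rose in 10 of 26 cases and fell in 2, with 14 not passing the test (12 and 3 adjusted over the list alone). The antigen transporter gene TAP1 rose by 1.48, ISG15 by 1.22 and RIGI by 0.84 (camera adjusted p = 0.0189, but adjusted p = 0.0635 with an estimated correlation).

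Genes of the cytosolic ribosome fell in 23 of 23 cases, with a median of -0.614 (camera adjusted p = 5.87e-21, and 0.0186 with an estimated correlation). RPL10A fell by 1.21 ± 0.05, RPL19 by 1.15, RPL8 by 1.05 and RPS9 by 0.94. TGF-beta and BMP pathway genes fell in 11 of 25 cases and rose in 5, with 9 not passing the test. LOX, a collagen cross-linking enzyme in the fibroblast list, fell by 2.53, TGFB2 by 1.87 and LTBP1 by 1.48, while the activin subunit gene INHBA rose by 2.57. The shift of the TGF-beta list (camera adjusted p = 0.0447) was not held with an estimated correlation (adjusted p = 0.0799 with an estimated correlation). Of 20 fibroblast and dedifferentiation genes, 8 fell, 3 rose and 9 did not pass the test, with CCN2 at -1.52, COL12A1 at -1.36 and PDGFRB at -0.92. The fibroblast list's shift (camera adjusted p = 0.0452) was lost with an estimated correlation (adjusted p = 0.111 with an estimated correlation), with the replicate block (adjusted p = 0.0514) and without replicate 1 (adjusted p = 0.113).

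The other lists were not called on average. In the Wnt pathway list, 7 of 20 genes fell, 1 rose and 12 did not pass the test (adjusted p = 0.0501), with AXIN2 at -0.74, SFRP5 at -1.14 and the antagonist gene DKK1 at 1.13. Of 23 hyaluronan and glycosaminoglycan genes, 10 rose, 5 fell and 8 did not pass the test (11 and 6 adjusted over the list alone; list adjusted p = 0.441). The hyaluronan receptor gene CD44 rose by 4.75 ± 0.15, while CSGALNACT1, an enzyme of chondroitin sulfate synthesis, and the hyaluronan synthase gene HAS2 fell by 2.08 and 1.13. Cell cycle genes rose in 7 of 28 cases and fell in 2, with 19 not passing the test, and the median of -0.030 differed in sign from the upward test (adjusted p = 0.441). The oxidative phosphorylation list had 6 of 20 genes higher, 4 lower and 10 not passing the test, and its median of 0.002 differed in sign from the downward test (adjusted p = 0.922). Of 22 immediate-early and dissociation genes, which can respond to tissue digestion, 12 fell, 5 rose and 5 did not pass the test (adjusted p = 0.105). NR4A1 fell by 1.97, EGR3 by 1.75 and EGR2 by 1.03, while KLF6 rose by 1.79.

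Marker lists of the cell types that an explant could hold were tested in the same way. Chondrocyte markers fell in 5 of 10 cases, with 5 not passing the test (6 lower adjusted over the list alone) and a median of -0.770 (camera adjusted p = 9.47e-05, and 0.0462 with an estimated correlation). All of these markers but SOX9 are also in the cartilage matrix list, so that this result is not separate from that of the matrix genes. No list of another cell type was called on average. The macrophage and monocyte list had 2 of 12 genes higher, 1 lower and 9 not passing the test (2 and 0 adjusted over the list alone; list adjusted p = 0.728), with FCER1G, a signalling chain of Fc receptors, at 3.44 ± 0.11. Osteoclast markers rose in 2 of 7 cases (adjusted p = 0.424), with the protease gene CTSK at 1.48 and the proton pump gene ATP6V0D2 at 1.91. The adjusted p was 0.992 for synovial lining and fibroblast markers (3 of 11 higher, 2 lower), 0.275 for osteoblast and osteocyte markers (0 of 7 higher, 3 lower) and 0.728 for lymphocyte markers (1 of 11 higher, 2 lower). It was 0.275 for endothelial markers (0 of 9 higher, 3 lower), 0.547 for red cell markers (0 of 5 higher, 1 lower) and 0.992 for adipocyte and muscle markers (0 of 9 called by limma, with 1 higher and 1 lower at an unadjusted p under 0.05).

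In the limma test of the average over days, 7991 of 25923 probe sets (30.8%) passed an adjusted p of 0.05, 4036 higher and 3955 lower, and 1083 of them differed at least 2-fold. They covered 6451 named genes. Which direction prevailed depended on the setting, with 4358 higher and 4515 lower with the replicate block and 3871 higher and 2962 lower with dim probe sets left out. Without replicate 2 the count was 5239. The gene list test called 15 lists with the preset correlation, 10 upwards and 5 downwards, and 8 lists with an estimated correlation.

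**Figure D2:**
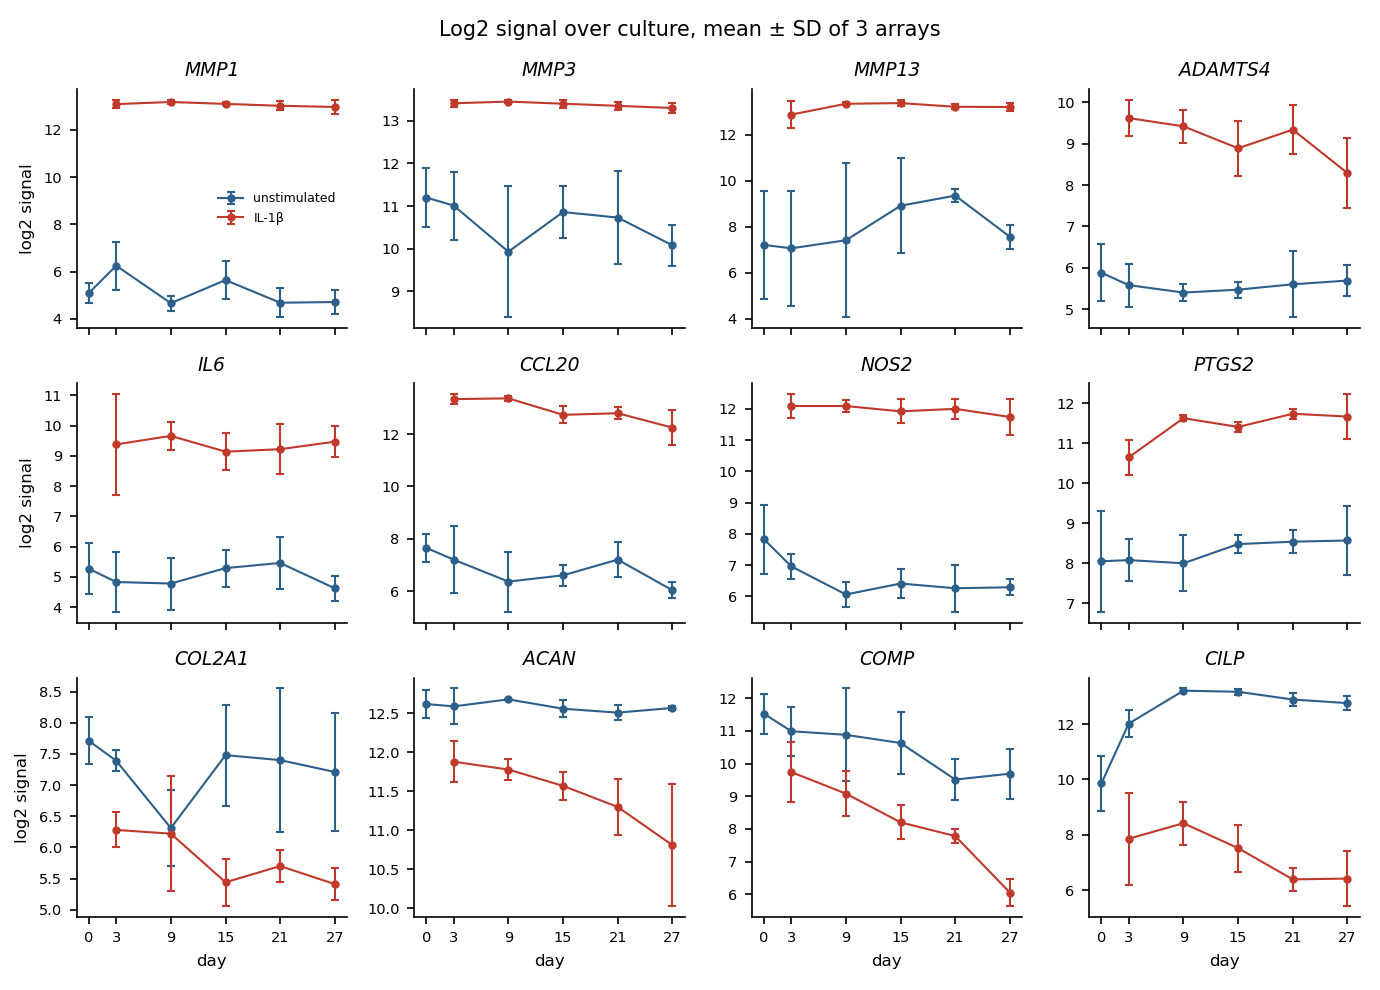
Log2 signal of 12 genes (vertical axes) against the day of culture (horizontal axes), with points and bars giving the mean and SD of 3 arrays of stimulated (red) and unstimulated (blue) explants. MMP1 stays near 13 with IL-1β and between 4 and 7 without it, while ACAN, COMP and CILP are lower with IL-1β at each day.

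At each day the same kind of comparison was made between 3 stimulated and 3 unstimulated arrays. Proteases, chemokines and NF-kB genes were shifted upwards and cartilage matrix and ribosomal genes downwards at all 5 days, with the preset and with an estimated correlation. Between 8 and 12 of 26 proteases, 4 and 8 of 16 chemokines and 12 and 17 of 23 NF-kB genes rose at a given day. The largest of the camera adjusted p was 0.00172, for the proteases at day 27, with an adjusted p of 0.0499 with an estimated correlation. At day 3, S100A12 rose by 7.24, MMP1 by 6.84 ± 0.38, C1H15orf48 by 6.45, CCL20 by 6.14 and PTX3 by 5.75 ± 0.33. Falls at day 3 included those of COL10A1, at -4.67 ± 0.94 (adjusted p = 0.00321), CILP at -4.16, APOA1 at -4.15, the matrix protein gene THBS4 at -4.12 and the small proteoglycan genes EPYC and OGN at -3.40 and -3.18. The calls of COL10A1, EPYC and OGN at day 3 were lost without replicate 1 (adjusted p of 0.0859, 0.161 and 0.151) and without replicate 3 (0.0759, 0.102 and 0.122). That of THBS4 was lost without any of the 3 replicates (0.166, 0.0518 and 0.111). At day 9, MMP1 rose by 8.52 and CCL20 by 7.005, while SLC14A1 fell by 5.66, BHMT by 4.81 and the lipocalin gene APOD by 4.71. At day 15, CYP1A1, a xenobiotic-metabolising cytochrome, rose by 6.53 ± 0.55, and CHRDL2, CRISPLD1 and the cytokine-like gene CYTL1 fell by 6.49, 5.32 and 5.17. At day 21, CHRDL2 fell by 7.11, CILP by 6.49 and IGSF10 by 5.55. At day 27, CXCL1 rose by 5.97, while SLC14A1 fell by 6.58, CILP by 6.34, OMD by 5.71 and the proteoglycan gene LUM by 5.45.

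MMP3, MMP13, ADAMTS4, IL6, CXCL6, CCL20, PTGS2, NOS2, TNFAIP6 and LIF were each called higher at all 5 days. For MMP13 the difference ranged from 3.86 at day 21 (adjusted p = 0.0316) to 5.93 at day 9 (adjusted p = 0.0014), and its calls at days 3, 9, 15 and 21 were lost without replicate 1 (0.0913, 0.0537, 0.198 and 0.154) or 2 (0.236, 0.161, 0.0992 and 0.207). Calls of TNFAIP6 at all 5 days were lost without replicate 2, with adjusted p from 0.118 at day 15 to 0.612 at day 3, and those at days 3 and 21 also without replicate 1 (0.194 and 0.0922). Those of MMP3 at day 3 without replicate 1 or 2 (0.136 and 0.215) and at day 15 without replicate 1 (0.0771), and of LIF at day 3 without replicate 1 or 3 (0.113 and 0.0574), were lost too. CXCL8 was called from day 9 onwards. ADAMTS5 was called at day 27 alone, at 2.18 ± 0.61 (adjusted p = 0.0142), and the call was lost without any of the 3 replicates (0.059, 0.0821 and 0.0657).

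The main matrix genes passed the test at some days only. ACAN differed by -0.71 at day 3 (adjusted p = 0.113) and was called from day 9, at -0.90, to day 27, at -1.76 (adjusted p = 4.73e-06). Its calls were lost at days 9, 15 and 21 without replicate 2 (adjusted p of 0.373, 0.167 and 0.103) and at day 9 without replicate 3 (0.0545). COL2A1 differed by -1.10 at day 3 (adjusted p = 0.338) and by -0.09 at day 9, and was called at days 15, 21 and 27, at -2.04, -1.70 and -1.80, with calls lost without replicate 1 (0.0928, 0.136 and 0.254) or 2 (0.111, 0.444 and 0.111), where the day 21 value was -1.04. COMP differed by -1.25 at day 3 (adjusted p = 0.38). It was called at day 15, at -2.43 (adjusted p = 0.00521), and at day 27, at -3.64 (adjusted p = 5.78e-05), with the day 15 call lost without replicate 1 or 2 (0.124 and 0.0626). With the replicate block, COMP was also called at days 9 and 21 (adjusted p of 0.00403 and 0.00383). TIMP1 was called at day 9, at 0.92, and day 15, at 0.89, with both calls lost without replicate 2 (0.163 and 0.114) or 3 (0.124 and 0.0738), and with the replicate block also at days 3 and 21 (0.0311 and 0.0287). SAA1, an acute phase gene, was called at no single day. COL10A1 was called at day 3 only.

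**Figure D3:**
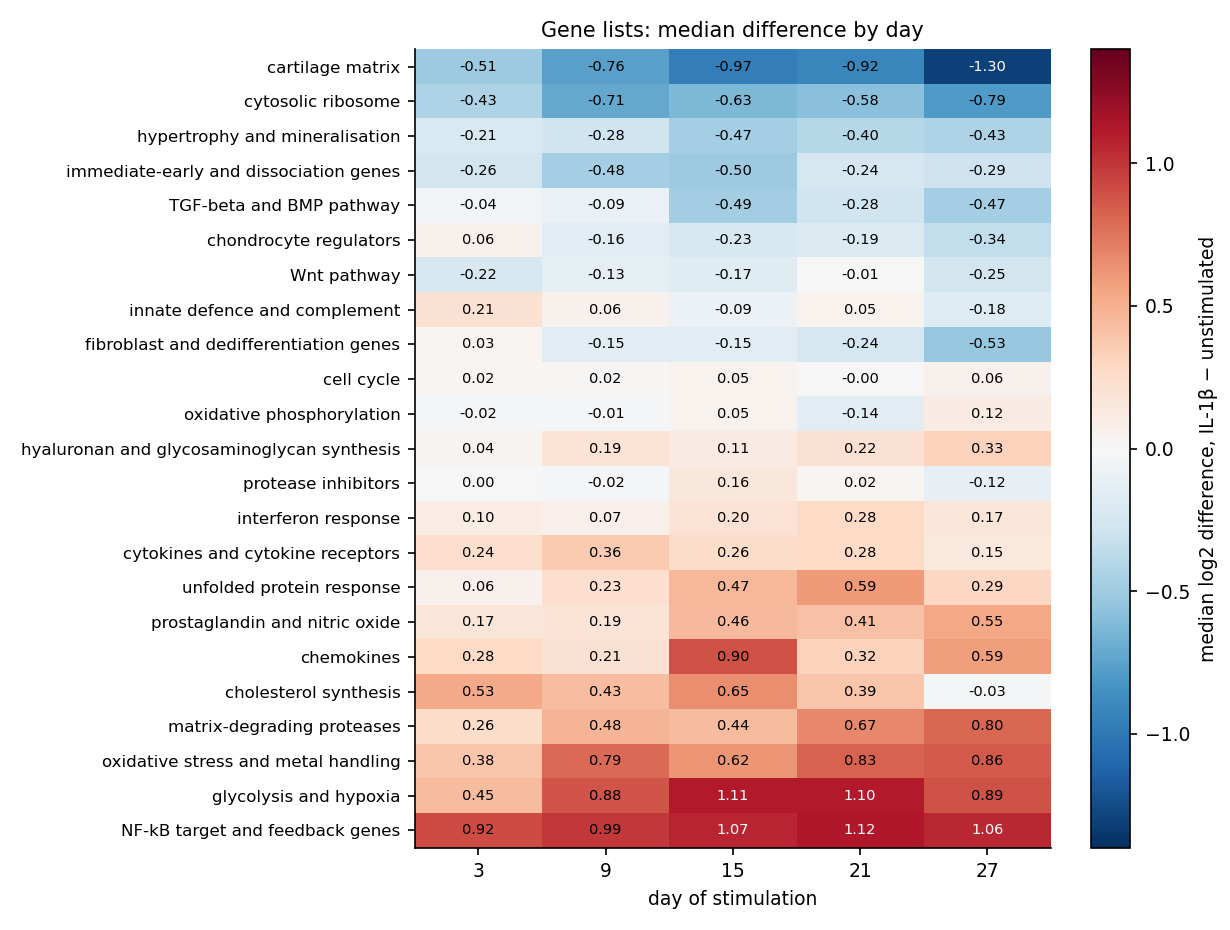
Median log2 difference between stimulated and unstimulated explants for 23 gene lists (vertical axis) by day of stimulation (horizontal axis), with red for higher and blue for lower in stimulated explants. The cartilage matrix median is -0.51 at day 3 and -1.30 at day 27, and the NF-kB median lies between 0.92 and 1.12.

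NF-kB target and feedback genes rose in 12 of 23 cases at day 3 (15 adjusted over the list alone) and in 17 at day 21 (18 adjusted over the list alone), with medians of 0.918 and 1.12 (camera adjusted p = 2.44e-17 and 4.27e-12, held with an estimated correlation). Cartilage matrix genes fell in 8 of 33 cases at day 3 (12 adjusted over the list alone) and in 22 at day 27 (25 adjusted over the list alone), where the list's camera adjusted p was 1.39e-10 and 1.92e-16, held with an estimated correlation. Glycolysis and hypoxia genes rose in 5 of 27 cases at day 3 (9 adjusted over the list alone), where the camera adjusted p of 3.95e-06 became an adjusted p = 0.115 with an estimated correlation. They rose in 20 at day 21 (22 adjusted over the list alone), where the median was 1.10 (camera adjusted p = 3.09e-13, and 0.0153 with an estimated correlation). Ribosomal protein genes fell in 13 of 23 cases at day 3 and in 22 at day 27 (20 and 23 adjusted over the list alone). At day 27, fibroblast and dedifferentiation genes fell in 10 of 20 cases (10 adjusted over the list alone), with a median of -0.531 (camera adjusted p = 0.000477, and 0.0134 with an estimated correlation). The innate defence list was called upwards at day 3, with 4 of 20 genes higher and 1 lower (5 and 1 adjusted over the list alone) and a median of 0.21 (adjusted p = 0.000217, 0.0471 with an estimated correlation and 0.000757 with the replicate block). It was also called upwards at day 9 (adjusted p = 0.0346), but not with an estimated correlation (adjusted p = 0.21 with an estimated correlation) or the replicate block (adjusted p = 0.068).

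In limma, 860 probe sets passed at day 3 (460 higher, 400 lower), 1954 at day 9 (1013 and 941), 3284 at day 15 (1760 and 1524), 3144 at day 21 (1584 and 1560) and 3833 at day 27 (2138 and 1695). The counts without replicates 1, 2 and 3 were 358, 217 and 448 at day 3, 1271, 638 and 1239 at day 9, 1986, 1293 and 2290 at day 15, 1660, 1548 and 2262 at day 21, and 2330, 1890 and 2603 at day 27. At days 9, 21 and 27 the excess of higher over lower calls depended on the setting. It turned at day 9 without replicate 2 (285 higher, 353 lower) and with quantile normalisation once more (985 and 1012), and at day 21 without replicate 1 (804 and 856), without replicate 2 (701 and 847), with only the arrays compared (1197 and 1299) and at least 2-fold (684 and 753). At day 27 it turned without replicate 3 (1281 and 1322) and without the unstimulated array of that replicate at day 27 alone (1368 and 1374). At all 5 days, 580 probe sets were called, 302 higher and 278 lower, and 5960 were called at 1 or more days. Between days 3 and 27, which share no array, 665 probe sets were called at both, 339 of them higher at both and 319 lower at both, where independent lists of those sizes give 37.9 and 26.2. The lists are not independent, since both days share the replicate numbers and the estimate of the spread of each probe set. Those counts are therefore a reference and no test. The correlation of the log2 differences across probe sets, which are not independent replicates, ranged from 0.594 between days 3 and 27 to 0.81 between days 15 and 21.

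**Figure D4:**
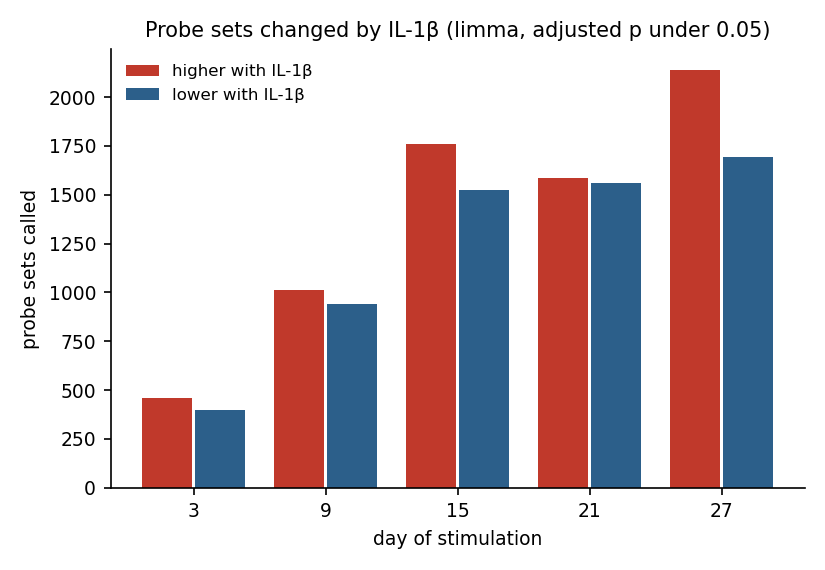
Number of probe sets passing an adjusted p of 0.05 in limma (vertical axis) at each day of stimulation (horizontal axis), with red bars for probe sets higher and blue bars for those lower in stimulated explants. The total is 860 at day 3 and 3833 at day 27.

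The time course also allows a test of whether the difference between stimulated and unstimulated explants itself changed. Between days 3 and 27, the difference shifted downwards for the cartilage matrix list, and 8 genes with a lower and 8 with a higher difference at day 27 were named by size, none of which kept its call without replicate 2. For CHRDL2 it fell by 5.44 ± 0.99 (adjusted p = 0.00447), with unstimulated explants at 6.59 ± 0.81 and 11.96 ± 1.38 and stimulated explants at 5.15 ± 0.35 and 5.08 ± 0.19 (SD, n = 3 each). For ALPL it fell by 4.66 (adjusted p = 0.00309), with unstimulated means of 5.29 and 9.46 and stimulated means of 4.95 and 4.46. GREM1, another BMP antagonist, went from 8.96 to 12.26 without IL-1β and from 9.91 to 8.49 with it, a change in the difference of -4.71 (adjusted p = 0.0169). BMP6 had a difference of 1.37 at day 3 and of -2.52 at day 27. The difference changed by -4.06 for PEBP4, -4.05 for TPRG1, -3.77 for CYTL1 and -3.64 for SIDT1. CCL5, a T-cell chemokine, moved by 3.38 ± 0.61 (adjusted p = 0.00405), with stimulated explants at 4.87 ± 0.09 and 8.58 ± 1.42 and unstimulated means of 4.11 and 4.44.

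Probe sets annotated to the microRNA precursors MIR29A and MIR29B had a change in the difference of 4.88 ± 0.74 (adjusted p = 0.00132) and 4.02 ± 0.73 (adjusted p = 0.00447). The level of MIR29A went from 4.85 to 8.14 with IL-1β and from 5.13 to 3.55 without it. AOAH, an enzyme that inactivates lipopolysaccharide, went from 3.79 to 6.71 with IL-1β, and the cathepsin gene CTSC from 3.73 to 6.32. The serine protease gene HTRA3 went from 8.80 to 5.25 without IL-1β. The change in the difference was 3.22 for RAB27B, 3.13 for HTRA3, 2.92 for CTSC, 2.82 for AOAH and 2.80 for TM4SF19. The smallest adjusted p for any difference between the 5 days was 7.65e-06, for BOC, a hedgehog coreceptor, whose difference was -0.84 at day 3 and -4.21 at day 27. CNMD followed, at -2.10 and -4.39 (adjusted p = 0.000619). ENOSF1, the laminin gene LAMA4 and the intermediate filament gene VIM were higher with IL-1β at day 3, at 1.40, 0.65 and 0.70, and lower at day 27, at -1.18, -1.22 and -0.89.

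**Figure D5:**
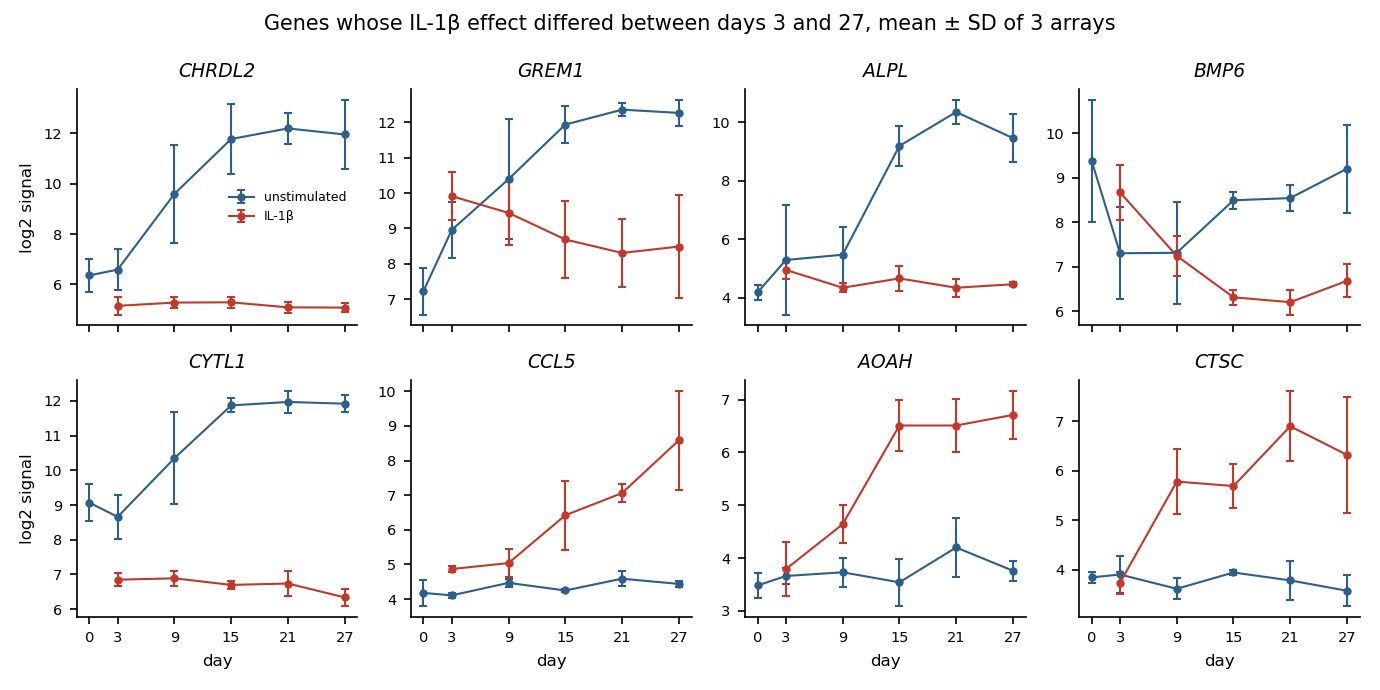
Log2 signal of 8 genes whose difference changed between days 3 and 27 (vertical axes) against the day of culture (horizontal axes), with points and bars giving the mean and SD of 3 arrays of stimulated (red) and unstimulated (blue) explants. CHRDL2 rises in unstimulated explants from 6.59 at day 3 to 11.96 at day 27, and CCL5 in stimulated explants is at 4.87 and 8.58 at the same days.

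Shifts of lists between days 3 and 27 were not tested with a replicate left out. The cartilage matrix list shifted downwards between days 3 and 27, with 4 of 33 genes lower (13 adjusted over the list alone) and a median of -0.696 (camera adjusted p = 9.73e-10, and 0.00953 with an estimated correlation). Its members with the smallest p included FMOD at -2.77, DCN at -1.97 and BGN at -1.97, all genes of small leucine-rich proteoglycans. Chondrocyte regulators fell in 4 of 17 cases (6 adjusted over the list alone; camera adjusted p = 0.00273, and 0.0439 with an estimated correlation), with FRZB at -2.19. Fibroblast genes fell in 3 of 20 cases (4 adjusted over the list alone; camera adjusted p = 0.00013, and 0.00953 with an estimated correlation), with PDGFRB at -1.55 and TAGLN at -1.79. Chondrocyte markers and the TGF-beta list were lower as well (adjusted p = 0.000105 and 0.0119, and 0.0479 and 0.0439 with an estimated correlation). The chondrocyte markers other than SOX9 are members of the cartilage matrix list too, so that their shift is not a separate result. Osteoblast and osteocyte markers, which include ALPL and COL1A1, shifted downwards with 1 of 7 lower (2 adjusted over the list alone) and a median of -0.109 (camera adjusted p = 0.0266, but adjusted p = 0.0935 with an estimated correlation). Chemokines moved upwards, with 2 of 16 genes higher (5 adjusted over the list alone) and CXCL14 at 1.89 (camera adjusted p = 0.0206, but adjusted p = 0.208 with an estimated correlation).

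In limma, 284 probe sets differed between days 27 and 3 (117 with a higher and 167 with a lower difference), and 106 differed between any of the 5 days. With the replicate block the counts were 496 (232 higher, 264 lower) and 233. Without replicates 1, 2 and 3 they were 21, 1 and 166 for days 27 and 3, and 9, 1 and 51 for any of the days. Of the 21, 11 were higher and 10 lower, whereas of the 166, 37 were higher and 129 lower. All 16 genes named for this comparison by size lost their call without replicate 2, where their smallest adjusted p was 0.163 (AOAH, CYTL1, PEBP4 and SIDT1). Without replicate 1, 12 of them did, with adjusted p from 0.0698 (TM4SF19) to 0.295 (RAB27B), and without replicate 3 there were 4, with adjusted p from 0.0516 (HTRA3) to 0.0984 (CTSC).

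Unstimulated explants give the background of change in culture. Between days 0 and 3, CYP1A1 rose by 3.49 ± 0.55 (adjusted p = 0.00248), APOA1 by 2.89 ± 0.45, the peptidase gene MME by 1.74, SAA1 by 1.61 and CNMD by 1.23. The cell adhesion gene CDH1 fell by 2.65 ± 0.34 (adjusted p = 0.000409), MIR29B by 2.75, CD55, a complement regulator, by 2.64, S100A2 by 2.33, IGFBP5 by 2.10 and the chromatin gene HMGA1 by 2.06. Innate defence genes shifted upwards with 1 of 20 called (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00962, but adjusted p = 0.302 with an estimated correlation). Glycolysis and hypoxia genes shifted upwards with 0 of 27 called by limma (0 adjusted over the list alone, and 2 at an unadjusted p under 0.05; camera adjusted p = 0.00962, but adjusted p = 0.556 with an estimated correlation). Immediate-early genes shifted upwards with 0 of 22 called by limma (2 adjusted over the list alone, and 5 at an unadjusted p under 0.05; camera adjusted p = 0.0157, but adjusted p = 0.556 with an estimated correlation). In limma, 104 probe sets were called, 28 higher and 76 lower, and 179 with the replicate block. The counts without replicates 1, 2 and 3 were 2, 0 and 22. It was also 0 when only the 6 arrays compared were fitted, and 2212 probe sets then had an unadjusted p under 0.05, against 1420 without replicate 2. All 16 genes named for this comparison by size lost their call in these last settings and without replicate 1, where CYP1A1 had an adjusted p of 0.117 and CDH1 of 0.0763. Without replicate 3, 7 of them did, among them MME (0.0757), SAA1 (0.233), whose value went from 1.61 to 0.72, and CNMD (0.349).

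Between days 3 and 27 in unstimulated explants, CHRDL2 rose by 5.37 ± 0.70 (adjusted p = 0.000119), ALPL by 4.17 ± 0.57, PEBP4 by 3.96, GREM1 by 3.30 and ITM2A by 2.80. COL10A1 fell by 4.63 ± 0.94 (adjusted p = 0.0112), ANGPTL7 by 4.32, FGL2 by 3.55, EVI2A by 3.30, ADAMTS5 by 3.24 and the angiogenic factor gene ANGPT2 by 2.58. MMP1 fell by 1.54 (adjusted p = 0.047). Among immediate-early genes, NR4A1 rose by 2.08 and NR4A2 by 1.63. The unfolded protein response list shifted downwards with 1 of 19 genes lower (3 adjusted over the list alone; camera adjusted p = 0.0165, but adjusted p = 0.546 with an estimated correlation). In limma, 261 probe sets were called, 114 higher and 147 lower, and 447 with the replicate block (188 higher, 259 lower). The counts without replicates 1, 2 and 3 were 35 (21 higher, 14 lower), 44 (17 and 27) and 109 (56 and 53). At least 2-fold, 76 were higher and 72 lower, so that neither direction prevailed in every setting. The count was 113 without the day 27 array of replicate 3 that stood apart (67 higher, 46 lower), and 4 when only the 6 arrays compared were fitted, where 14 of the 16 genes named by size lost their call. Without replicate 1, 10 of the 16 did, with COL10A1 at an adjusted p of 0.206, ALPL at 0.114 and ADAMTS5 at 0.0974. Without replicate 2, 9 did, among them GREM1 (0.308) and ADAMTS5 (0.112), and without replicate 3, COL10A1 (0.129) and ANGPT2 (0.0799) did. Over all 6 times of unstimulated culture, 1208 probe sets differed (1838 with the replicate block, and 358, 271 and 441 without replicates 1, 2 and 3). CNMD (adjusted p = 5.79e-10), ALPL and NR4A1 (both 6.17e-08), the laminin receptor gene ITGA6 (6.43e-08) and the cross-linking enzyme gene LOXL3 (1.76e-07) had the smallest values.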

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

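The condition that the share described here hold without each replicate, the alternative without the day 27 array of replicate 3 and the test by the calls made without that array were chosen only after the result was seen. The results below drew attention because a test of the difference between days itself was passed, as an effect of IL-1β that was not the same at all days.

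In limma, 106 probe sets differed between any of the 5 days and 284 between days 27 and 3. Among the 106, the difference was opposite in sign at days 3 and 27 for 36. It was larger at day 27 for 30 of the 36 that were higher on average and for 66 of the 70 that were lower on average. When the days of the 15 pairs were relabelled, none of the other 99 of 100 relabellings gave more than 1 call. This does not exclude chance for the first count, because relabelled groups mix days of culture. Change over culture then adds to their spread and lowers their calls. For the second count the 10 splits of 6 pairs are too few for a share under 0.05, with 284 calls for the real split and 0 as the highest of the others. Without replicate 2 both counts were 1, without replicate 1 they were 9 and 21, and without replicate 3 they were 51 and 166.

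The day 27 minus day 3 change in the difference was 4.88 for MIR29A, 4.02 for MIR29B, 3.38 for CCL5, 3.22 for RAB27B, 3.13 for HTRA3, 2.92 for CTSC, 2.82 for AOAH and 2.80 for TM4SF19. It was -5.44 for CHRDL2, -4.71 for GREM1, -4.66 for ALPL, -4.06 for PEBP4, -4.05 for TPRG1, -3.90 for BMP6, -3.77 for CYTL1 and -3.64 for SIDT1. The adjusted p of a difference between any of the 5 days was 7.65e-06 for BOC, 0.000619 for CNMD, 0.00131 for ALPL, 0.00167 for the homeobox gene DLX5, ENOSF1 and LAMA4, 0.00204 for ENPP1 and AOAH, 0.00205 for VIM and 0.00213 for CYTL1.

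Gene lists shifted between days 3 and 27 too, with medians of -0.70 for cartilage matrix, -0.64 for chondrocyte regulators, -0.50 for fibroblast and dedifferentiation genes and -0.15 for the TGF-beta and BMP pathway, all of which held with an estimated correlation. The medians were -0.25 for hypertrophy and mineralisation, 0.37 for chemokines, -0.28 for innate defence and complement, 0.32 for glycolysis and hypoxia, 0.53 for oxidative stress and metal handling, -0.38 for cholesterol synthesis and -0.33 for the cytosolic ribosome. The shifts of these 7 lists were not held with an estimated correlation (adjusted p of 0.205, 0.208, 0.281, 0.415, 0.296, 0.547 and 0.208 with an estimated correlation). No list shift between days 3 and 27 was tested with a replicate left out.

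Of the 284 probe sets, 117 had a higher and 167 a lower difference at day 27, but which direction prevailed depended on the replicates. Higher and lower calls were 11 and 10 without replicate 1, 0 and 1 without replicate 2, 37 and 129 without replicate 3 and 56 and 148 without the day 27 array of replicate 3.

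The pattern weighed here is that the effect of IL-1β differed between days 27 and 3. The single array of unstimulated explants at day 27, replicate 3, as the source of all calls is argued against, since a fit without it called 204 probe sets, 165 of them among the 284. A part stays open, because higher calls went from 117 to 56 without it and the median size of the difference, 0.979 of its value, was taken over probe sets chosen with it. Change in the unstimulated explants alone may account for part, as their change was the larger for 37% of the called probe sets. A share under 40% had been set to exclude this, but the share ranged from 32.4% to 41.5% without each replicate. For the 167 with a lower difference, the median change was 0.64 without IL-1β and -0.9 with it. For the 117 with a higher difference, the medians were -0.49 and 0.74. Among named genes, the change lay mostly in the unstimulated explants for CHRDL2 and ALPL and in the stimulated ones for CCL5. A single horse stays open, because the 100% of called probe sets that kept their sign without each replicate were chosen for the pattern, and so does the length of stimulation, which the design names.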

How the results depend on the processing

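The alternative without the day 27 array was chosen only after the result was seen. Genes named by size for a contrast and the fixed genes were followed over the settings, and those named only from a list or an F-test were not. Of 259 such results, 218 were called and 140 of these were called with the same sign in every setting run. Leaving out a replicate and fitting only the arrays compared leave fewer samples, which lowers the power by construction. For all other changes the cause was not tested. Over the left-out replicates, the counts ranged from 217 to 448 at day 3, 638 to 1271 at day 9, 1293 to 2290 at day 15, 1548 to 2262 at day 21, 1890 to 2603 at day 27 and 5239 to 6583 for the average. They ranged from 1 to 166 for day 27 against day 3 and from 1 to 51 for any of the days. For unstimulated explants they ranged from 0 to 22 (days 0 and 3), 35 to 109 (days 3 and 27) and 271 to 441 (all times), and for lists from 15 to 18. Without the day 27 array of unstimulated explants, replicate 3, the counts were 928, 2119, 3544, 3364 and 2742 by day, 7731 for the average, 204 for day 27 against day 3, 106 for any of the days, and 106, 113 and 1194 for unstimulated explants. In limma the count of 0, without replicate 2, had 1420 at an unadjusted p under 0.05. With only the arrays compared, the counts were 354, 1102, 1916 and 1850 at days 3, 9, 15 and 27, and 0, 4 and 447 for unstimulated explants at days 0 and 3, days 3 and 27 and all times. That 0 had 2212 at an unadjusted p under 0.05 in limma, and at day 3 the share higher was 65.0% against 53.5%. At least 2-fold, the counts were 438, 941, 1392, 1437 and 1658 by day, 1083 for the average and 62 and 148 for the unstimulated contrasts. With the replicate block, the counts were 496 (day 27 against day 3), 233 (any of the days), 179, 447 and 1838 (unstimulated). The replicate block also ended the call of the fibroblast list on average (adjusted p = 0.0514, with a range of 0.0273 to 0.113 for the fibroblast and dedifferentiation genes over all alternatives) and it added 5 calls (TIMP1 at days 3 and 21, COMP at days 9 and 21, COL9A1 on average). It changed no other call among the 259 results or of a list on average. Between or at single days it ended the call of innate defence at day 9 (0.068). It also added those of interferon response at day 3 (0.0421) and the unfolded protein response for day 27 against day 3 (0.0412). Without the block, these 2 added lists had an adjusted p = 0.14 with an estimated correlation and an adjusted p = 0.551 with an estimated correlation. With a random block the counts were 398 (unstimulated, days 3 and 27) and 186 (any of the days), and with array weights 172 (unstimulated, days 0 and 3) and 194 (any of the days). With an estimated correlation 8 lists were called. On average over days, 1 list lost its call with each of array weights, dim probe sets left out and quantile normalisation once more. Dimmer probe sets left out, quantile normalisation once more, and trend and robust fitting moved none of the 12 counts by over 1.5 times. List calls on average were gained too, 3 without replicate 2 and 2 with dim probe sets left out. A gain of 1 list came with quantile normalisation once more, trend and robust fitting, without replicate 1 and without the day 27 array.

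Among the gene results and lists followed over the settings, those that changed sign were all uncalled in the reported fit. Over the left-out replicates, ADAMTS5 ranged from -0.08 to 1.29 at day 9 and from -0.18 to 0.14 at day 15, with 0.03 without replicate 3, and COL1A1 from -0.04 to 0.01 at day 9 and from -0.23 to 0.12 at day 15, with 0.07 without replicate 3. COL2A1 ranged from -0.34 to 0.17 at day 9, and SOX9 from -0.21 to 0.04 at day 9 and from -0.40 to 0.17 at day 27. COL9A1 at day 27 was -0.64 without replicate 2 and 0.05 without the day 27 array. The median of the oxidative phosphorylation list ranged from -0.027 to 0.073 and that of the protease inhibitors from 0.001 to 0.108 (0.012 without replicate 3, 0.051 without the day 27 array and -0.002 without dim probe sets), the sign here being that of the list test. With quantile normalisation COL1A1 became 0.05 at day 9 and 0.09 at day 15, and with array weights ADAMTS5 became 0.04 at day 15. Near the lowest signals, where signal over background was not used here, small differences are limited in both size and sign.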

Other observations

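The tests of housekeeping genes and of the 15 pairs for the ribosomal genes, the condition on day 0 signals for other cell types, and the 4 genes named for the horses were chosen only after the result was seen.

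The difference between stimulated and unstimulated explants varied between replicate numbers, taken as horses, for 4 probe sets in limma, all of them named genes. EPCAM, an epithelial adhesion gene, differed by -3.01 ± 0.47 in replicate 3 (SD over 5 days), where the unstimulated signal was 6.43 ± 0.67, against differences of -0.44 and 0.01 and unstimulated signals of 3.48 and 3.20 in replicates 1 and 2 (adjusted p = 0.00018). PLA2G2A, a secreted phospholipase of inflamed joints, differed by 3.61 ± 0.71 in replicate 3, from 7.55 ± 0.62, and by 0.50 and 0.56 in replicates 1 and 2, from 11.99 and 11.80 (adjusted p = 0.000477). KCNIP3, a calcium-binding repressor, differed by -0.56 ± 0.38 in replicate 2, where the unstimulated signal was 4.73, against -3.70 and -3.49 in replicates 1 and 3, from 8.51 and 8.76 (adjusted p = 0.0142). FGL1 differed by -3.49 ± 0.80 in replicate 2, from 6.94 ± 1.01, against -0.63 and -0.72 in replicates 1 and 3, from 3.83 and 4.20 (adjusted p = 0.0182). For each of the 4, the replicate whose effect stood apart also stood apart in the unstimulated explants. With IL-1β, replicates 1, 2 and 3 lay closer together, at 3.04, 3.21 and 3.41 for EPCAM and 3.20, 3.45 and 3.48 for FGL1. They were at 4.82, 4.18 and 5.27 for KCNIP3 and at 12.48, 12.37 and 11.17 for PLA2G2A. The differing effects thus went with differing levels without IL-1β, and a differing response was not told apart from these. No explanation was tested. When the numbers were relabelled within days, none of 99 others reached the count of 4 for the real numbers, but the highest gave 3. With so small a margin, chance for the count is argued against only weakly.

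Ribosomal protein genes were lower with IL-1β at every day, by a mean of -0.503 ± 0.031 at day 3, -0.739 ± 0.129 at day 9, -0.711 ± 0.095 at day 15, -0.654 ± 0.084 at day 21 and -0.863 ± 0.242 at day 27 (SD, n = 3). Compression or normalisation of bright probe sets could not be settled as a source. The list's median of -0.614 lay at percentile 0.29 of 10000 random lists of equal size matched on mean signal, whose median was -0.151. Those lists drew genes independently, whereas ribosomal genes vary together, with an estimated correlation of 0.482. The percentile therefore overstates how unusual the list's median is. A general shift of bright housekeeping genes could not be settled either. The medians of the glycolysis and oxidative phosphorylation lists did not fall, the lower being 0.00203. However, glycolysis genes themselves rose with IL-1β, oxidative phosphorylation genes went both ways, and neither list was matched on signal. The list mean was lower in the stimulated explant in 15 of 15 pairs, which restates the pattern and does not test its source, and IL-1β stimulation, the explanation that the design names, stays open. RNA quality and the efficiency of amplification were not analysed here and stay open.

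Along the first principal component, unstimulated explants moved away from stimulated ones up to day 15, with day 0 between. The correlation across probe sets between the change from day 0 to days 9 and 15 without IL-1β and the IL-1β effect, taken on other arrays, was -0.37, and -0.292, -0.283 and -0.289 within replicates 1, 2 and 3. Shared arrays or noise are argued against as the only source. Of 84 splits of the 9 unstimulated arrays, 1, the real one, gave a value as low, and the lowest other was -0.31. However, the unstimulated arrays within the IL-1β effect can carry the same lasting change of culture, which enters that effect with a minus sign. A negative correlation can then arise without a link to the response to IL-1β. The splits do not remove this, so that such a link could not be settled. A fading inflammatory state is argued against as far as NF-kB genes tell, whose median changed by -0.0489 (0.0526, -0.0788 and 0.224 within replicates), while loss of RNA of other cell types could not be settled, because the lowest median change among their marker lists was -0.0205 but 6 of those 8 lists lay under the array median at day 0 already, where a loss could hardly show, with only the synovial (5.40) and adipocyte and muscle (5.81) lists above it.

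Other splits of the samples were tested for each count. For the average over days, chance was excluded for arrays taken as independent, with 7991 calls against at most 1170 in the 99 other of 100 relabellings of stimulation within days. Each day was relabelled on its own, so that an effect particular to 1 replicate number is not covered. For lists with the preset correlation, no other relabelling reached the real count, but the margin was small, with 15 against at most 14. However, 84 of the 99 relabellings called 1 list or more with the preset correlation and a median of 4, while with an estimated correlation the 99 called 0 lists by camera against 8 for the real labels. Over all times of unstimulated culture, chance was excluded, with 1208 calls against at most 351. For single days, 10 splits of 6 arrays are too few for a share under 0.05. The real count and the highest of the others were 860 and 0 at day 3, 1954 and 0 at day 9, 3284 and 2 at day 15, 3144 and 1 at day 21, 3833 and 1 at day 27, and 261 and 1 for unstimulated explants between days 3 and 27. For unstimulated explants between days 0 and 3, where the splits are too few as well, 2 of 10 splits reached the real count of 104. The other, with 105, does not part all 3 pairs of the same number, and the highest among those that do was 0. With the replicate block the real count was 179.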
